A study of Mus musculus with 4 samples.

How the data were processed

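Nuclei were extracted from the medial prefrontal cortex of adult mice, per the labels' protocols. By the same protocols, they were made into 3' libraries of polyadenylated RNA with the 10x Genomics Chromium V3 chemistry. Of such libraries, 4 were analysed here. Their titles number them 3 and 4 within each treatment, and whether other libraries were made is not known here. Cell Ranger 2.2.0 and the mouse genome build mm10 are named in the submitters' processing notes, with no role given for either. Settings, filters and the gene annotation are not given in the sources used here. The 8 deposited files analysed here were, for each library, a list of barcodes (1 text column) and a list of genes (3 text columns: identifier, symbol and feature type). They carry no unit, since they hold names and no measured values. Counts per gene and barcode were not analysed here.

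Libraries were assigned to the antibiotic (n = 2) or control (n = 2) group by the treatment given in the labels. The design fixed before the data were examined was a test of counts summed per library, for each cell type and over all nuclei. It also held tests of the 7 gene lists and of the share of nuclei per cell type, and a rule for naming genes. The plan already described the data as barcode and gene lists, and made every test conditional on counts. None of these tests was run, because each needs counts, and the rule for naming genes was therefore not applied. The genes named in the report are examples from the marker lists. For shares of nuclei, 2 libraries against 2 could in any case not have reached the usual threshold in an exact permutation test.

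From the files, each list was read in Python 3.11.15 with NumPy 2.4.6. Its entries and distinct entries were tallied, each file was searched for any column cell that is a number, and the lists of the 4 libraries were compared line by line in file order and, as an alternative, as sets of entries. Gene identifiers were matched without version numbers to GENCODE M21, whose genome is GRCm38, the assembly that mm10 also names. No coordinates were taken from it. The fixed marker and gene lists were matched to the files' own symbols exactly. These steps involve no sampling, so they have no error or depth attached. The depth per library is unknown.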

Results

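Single-nucleus RNA sequencing was used to profile the medial prefrontal cortex of adult mice, a cortical region involved in learning to suppress fear, in 4 libraries. Of these, 2 libraries came from treatment with antibiotics, which deplete the intestinal microbiota, and 2 were controls. The design took each library as the nuclei of 1 mouse, with the mouse as the unit of replication (n = 2 per group). Going by the title of the series, the question was how the intestinal microbiota relate to neuronal function and to the extinction of learned fear.

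The files analysed here held no measured value. Of the 8 files, 0 had a column that contained a number. Each library was represented by a list of barcodes and a list of genes, and the counts that join genes to barcodes were not analysed here. The depth of each library, its number of nuclei, its cell types and the expression of any gene are therefore not reported. The comparison of antibiotic-treated with control mice was not made for any gene, gene group or cell type, and no fold change, share of nuclei or p-value is given.

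The list of genes was identical in the 4 libraries and held 27998 distinct Ensembl mouse gene identifiers, all of a single feature type, gene expression. It set which transcripts could be counted, not which were present. By identifier, 27722 of them (99.01%) were found in the GENCODE M21 annotation of the mouse genome and 276 were not. Among those found, 21631 were protein-coding genes, 3502 were long intergenic non-coding RNAs and 2282 were antisense RNAs. The list also held 13 symbols with the prefix of mitochondrially encoded genes. A total of 56 symbols were each carried by more than 1 identifier, covering 121 identifiers, so a symbol alone would not name 1 gene for these.

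The cell type markers fixed before the data were examined were all on the list, for 9 of 9 cell types. They comprised 6 markers of excitatory neurons (among them Slc17a7, a vesicular glutamate transporter), 8 of inhibitory neurons (among them Gad1 and Gad2, which make GABA), 6 of astrocytes, 6 of oligodendrocytes, 5 of oligodendrocyte precursors, 6 of microglia (among them Csf1r, a receptor on which microglia depend), 5 of endothelial cells, 6 of mural or fibroblast-like cells, and 5 of blood and other immune cells. The 7 gene lists fixed at the same time were also complete. They held 22 genes of synaptic and calcium signalling, 14 activity-dependent genes, 18 genes of microglial development and activation, 10 of myelination, 12 of oxidative phosphorylation, 12 of cytosolic ribosomal proteins, and 14 of axon guidance and adhesion. None of these symbols was shared by more than 1 identifier. Being on the list says nothing about whether a gene was detected in any mouse.

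The list of barcodes was likewise identical in the 4 libraries, with 6794880 distinct barcodes of 16 bases in each. The list was not compared with a reference list of barcodes. Being the same in every library, it does not tell which barcodes held a nucleus, and its length is not a number of nuclei.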

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

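How far any result depends on the processing was not tested. The lists were byte-identical in the 4 libraries, so comparing them as sets of entries instead of line by line had to give the same 6794880 barcodes and 27998 genes, and it says nothing about stability. No alternative that needs counts per gene and barcode was run. These would include another tool and normalization, no filter on low counts, and each replicate left out in turn. They would also include a stricter minimum of genes per nucleus, another clustering resolution, and the planned estimated correlation in the gene list tests. The planned tests held no pairing between the groups, and none of them was run.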

Other observations

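The software version and the layout of the lists differ in period. Cell Ranger 2.2.0 is the version named in the submitters' processing notes, while a gene list with a feature type as the last of its 3 columns is, as background, the layout introduced with a later major release of that software. Which version made the lists was not tested.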
